A study of Homo sapiens with 3 samples.

How the data were processed

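Gene expression was compared on 3 two-colour oligonucleotide arrays, each carrying 45220 features. Per the labels, every array held RNA of MCF10A cells, an immortalised non-tumorigenic breast epithelial line, that stably expressed an shRNA against obscurin, coupled to Cy5 as channel 1. Channel 2, coupled to Cy3, held RNA of the same line with a scrambled control shRNA. Both cultures had received 150 uM etoposide for 48 hours, and the labels call the 3 arrays independent replicates. The dye assignment was the same on all 3 arrays, so a dye effect could not be separated from the shRNA.

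The deposited values are log2 ratios of both channels, one per feature and array. The scanner, image analysis and normalization are not given in the sources used here, and channel intensities were not used here. The base of the logarithm was read from the values. On each array the highest value, shared by 35, 51 and 39 features, lay 16.61 above the most frequently repeated value, which is the log2 of 100000. That distance would arise from a ratio limited at 100000 before each array was multiplied by a constant, 4.18, 3.92 and 3.99 on arrays 1, 2 and 3. No header or label records such a step. Of scale, centring and direction, the centring and the direction stay unknown. The direction was taken as likely obscurin shRNA over control shRNA, because the former is channel 1.

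Features were named through the array's platform annotation, with symbols updated by Entrez identifier to the names of the GRCh38.p14 RefSeq gene table. Of 31332 features with 1 symbol, 31291 matched by identifier and 0 changed symbol. Another 93 features had several symbols and 13795 had none, and these stayed out of gene results. The features of a symbol were averaged on each array, using those with a value. This gave 18334 genes, of which 12550 had a value on all 3 arrays and were tested. Values at an array's highest value touched 125 features and 89 genes, and are bounds if the ratio was limited. The number of arrays limits the precision.

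The mean log2 ratio of each gene was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 34 gene lists were tested against the other genes with camera at a preset correlation of 0.01, two-sided, for lists with at least 5 measured genes. The result of 1 list and of 1 gene set beforehand is not reported here. The lists, the tests and the first group of other settings below were set before the data were examined. The genes named in the text were the 12 genes in each direction with the largest mean among those past the threshold with the same sign on all 3 arrays. Places left open went to the smallest unadjusted p in that direction with the same sign on all arrays, with uncharacterised symbols passed over (0 were met in either direction). From each list, up to 4 members past the threshold were to be named, or else up to 2 with the smallest p, as values. Any other gene in the text was chosen after its values were seen, as stated there.

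Whether the row of a value matched the annotation of its feature was checked with 236 transcripts annotated to at least 10 features each. Their 2466 features should rank alike on an array. The distance between neighbouring feature rows, 170 features, was taken as the displacement, of up to 600, at which an array correlated best with itself. The feature list was divided into 5 consecutive stretches of 9044 features. In each stretch, the rank of each repeated feature was correlated with the mean rank of the other features of its transcript on arrays 2 and 3 in the first stretch, at the own place and at displaced places. Standard errors came from 300 bootstrap resamples of transcripts. The intraclass correlation of repeated features within a stretch, which needs no reference from elsewhere, was taken at the own place and 1 row earlier too. The rank correlation between arrays over the features of other transcripts was taken with 1 array displaced, with 300 resamples of features. These checks were added after the data were seen. The correlation and the intraclass correlation each recovered the better place of 15 of 15 stretches on simulated data. Those data had 1 displacement per stretch and transcript differences as wide as the noise. They do not show how reliably the place is found in the real data.

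The gene test was also checked on simulated data with 12550 genes and the spread of the real ones. In 5 runs it recovered 0 of 250 genes moved by a log2 ratio of 1, 0 of 250 moved by 2, 0 of 250 moved by 4 and 0 of 250 moved by 6, with 0 false calls. With a spread of 0.3 between arrays it recovered 200 of 200 genes moved by 2, with 7 false calls. With the real spread, a count of 0 genes therefore does not show absence of change, also where other settings repeat it. The runs do not show how many changed genes the test recovers in the real data. With the list of ribosomal protein genes moved by 1, camera recovered it in 20 of 20 runs, with 2 false calls of other lists. Genes were drawn independently in these runs, whereas the real list had an estimated correlation of 0.262. The runs therefore do not show how often camera at the preset correlation falsely calls a list of correlated genes.

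Other settings were centring each array on its median, scaling arrays to equal median absolute deviation, quantile normalization, values on at least 2 arrays, a minimum mean of 1, testing each feature on its own, the median of spots, robust eBayes, array weights, a 1-sample test without moderation, leaving out each array, camera with an estimated correlation or on ranks, and fry. Settings added after seeing the data treated values at the top as missing, used only spots with values on all 3 arrays, set each array to 0 at its most repeated value, tested named features on their own, centred each array on its median over tested genes, or took values from displaced places. The 3 arrays leave 2 residual degrees of freedom. Whether camera with an estimated correlation can call any list then was not tested, so a call lost there is weak evidence against it.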

Results

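The study asked how loss of obscurin, a giant cytoskeletal signalling protein, alters gene expression in MCF10A breast epithelial cells exposed to etoposide, a topoisomerase II poison that breaks DNA. RNA of cells with an obscurin shRNA and of cells with a control shRNA was hybridised together on each of 3 arrays, after 48 hours in 150 uM etoposide. There was 1 comparison, measured once per array. Of 45220 features, 36065, 35502 and 35674 had a log2 ratio on arrays 1, 2 and 3, and 23308 had one on all 3. Signed values are likely obscurin shRNA over control shRNA, since the obscurin shRNA cells are channel 1; the direction in which the ratio was formed is not stated.

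Most log2 ratios lay above 0. The median over features was 1.49, 1.28 and 1.39 on arrays 1, 2 and 3, and 67.3%, 65.2% and 67.1% of features were above 0. The values formed a narrow peak near 2, with 39.7%, 36.1% and 38.9% of features within 0.5 of the most repeated value (2.06, 1.97 and 2.00), and a broader peak between -1.25 and -1.0 on array 1 and between -1.75 and -1.5 on arrays 2 and 3 (bins of 0.25). A log2 ratio of 0 therefore fell between both peaks and did not mark the bulk of the features. For this reason the medians of gene lists are given relative to each array's median over the tested genes, which was 1.02, 0.80 and 0.90. Values of single genes are as deposited unless stated otherwise, so a list median and its members stand on different scales below.

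**Figure D1:**
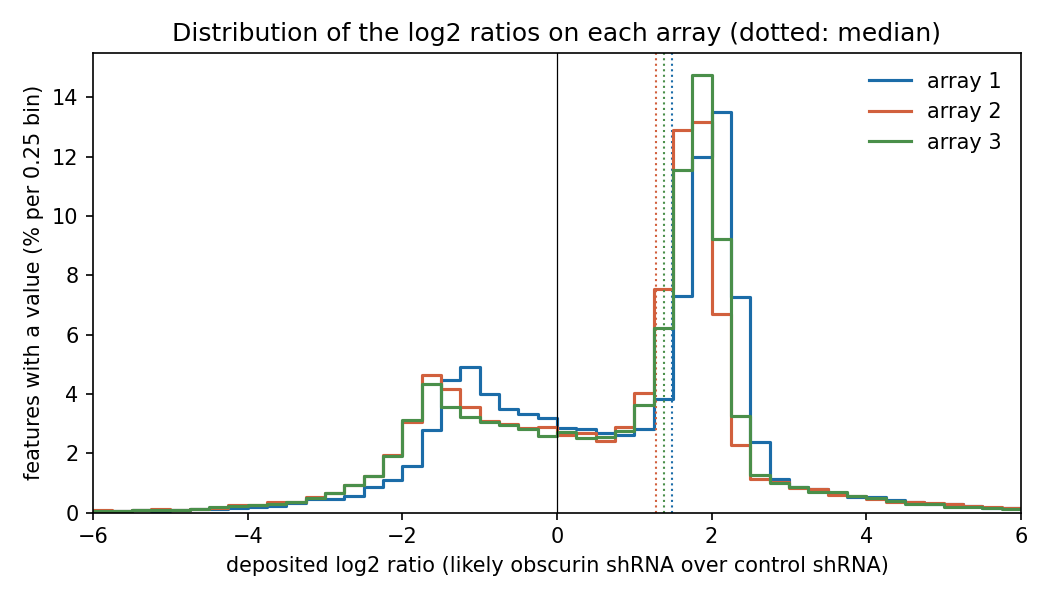
Share of features with a value (y axis, percent per bin of 0.25) against the deposited log2 ratio (x axis, log2), with 1 line per array and a dotted line at its median. All 3 arrays show a narrow peak near 2 and a lower, broader one below 0, with medians of 1.49, 1.28 and 1.39.

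The arrays agreed in part. Across features, which are not independent replicates, the rank correlation was 0.342 between arrays 1 and 2, 0.267 between arrays 1 and 3, and 0.532 between arrays 2 and 3. Features annotated to one gene hardly resembled each other: their intraclass correlation was 0.031, 0.032 and 0.028 on arrays 1, 2 and 3. For the 236 transcripts with at least 10 features, the intraclass correlation of ranks was 0.079, 0.107 and 0.104 at the feature's own place, and 0.160, 0.147 and 0.125 when each value was taken from 170 features, or 1 feature row, earlier. With permuted annotations each of these 6 values had p = 0.001, the smallest that 1000 permutations can give. The better place differed along the arrays. On array 1 it lay 1 row earlier in the first of 5 consecutive stretches of 9044 features, with a correlation of 0.482 ± 0.051 (bootstrap SE) against 0.172 ± 0.054 at the own place. On arrays 2 and 3 the own place was better in the first stretch, at 0.578 ± 0.055 and 0.562 ± 0.050, and 1 row earlier was better in the last stretch, at 0.328 ± 0.052 and 0.451 ± 0.048. The reference came from arrays 2 and 3 at their own place in the first stretch, which favours the own place there. The intraclass correlation, which needs no reference, was also higher at the own place there, by 0.680 ± 0.079 on array 2 and 0.536 ± 0.089 on array 3. Of the 15 stretches (5 on each of 3 arrays), 7 agreed better 1 row earlier by more than 2 SE, 3 agreed better at the own place and 5 were open. In 0 of the 5 stretches was the own place better on all 3 arrays, so the gene names below are those of the annotation at the own place and were not borne out over much of the arrays.

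**Figure D2:**
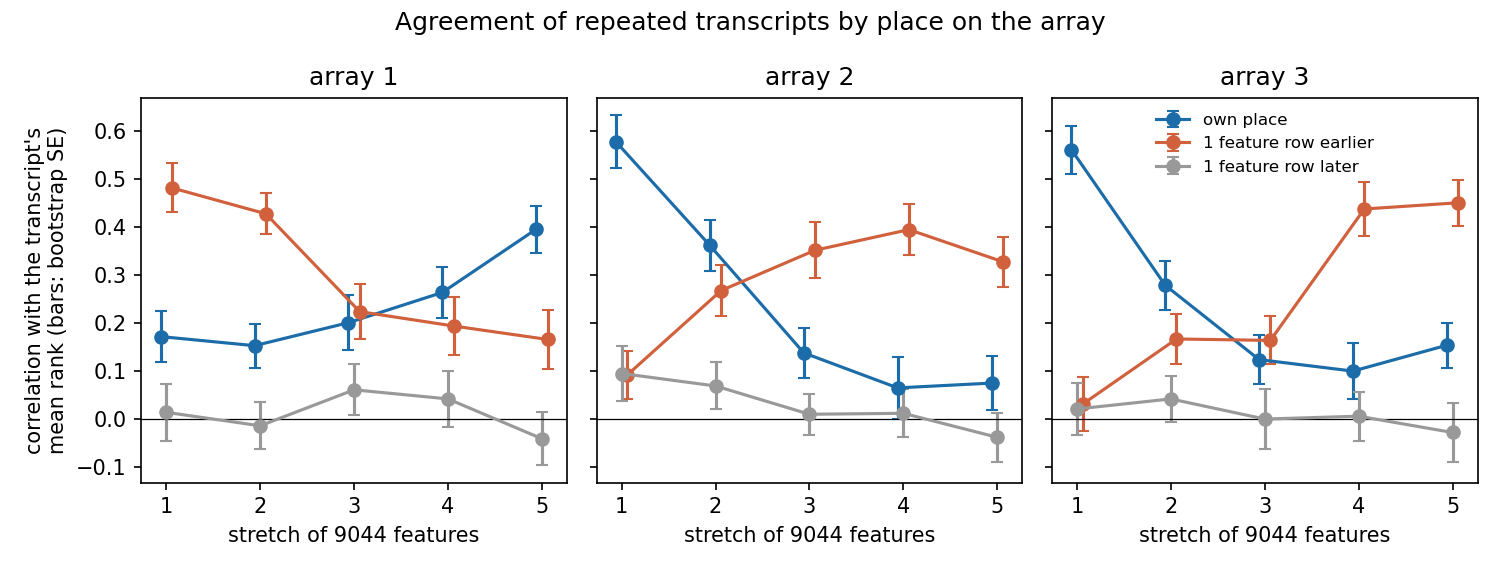
Correlation of repeated features with the mean rank of their transcript (y axis) by stretch of 9044 features along the feature list (x axis), 1 panel per array, at the annotated place, 1 feature row earlier and 1 feature row later; bars are bootstrap SE. On array 1 agreement moved from 1 row earlier (0.482) to the own place (0.396) along the list, and on arrays 2 and 3 from the own place (0.578 and 0.562) to 1 row earlier (0.328 and 0.451).

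No gene passed the threshold for a difference between cells with obscurin shRNA and cells with control shRNA, tested against 0 as deposited. This depended on the zero point: with each array set to 0 at its most repeated value, chosen after seeing the data, 2 passed above and 2161 below. With the values as deposited, all places went to the smallest p. The 12 genes given here on each side were therefore taken by p and not by size. Above 0, the smallest p belonged to features annotated to MXRA5, an extracellular matrix protein, and SAPCD2, a regulator of spindle orientation. MXRA5 had a mean log2 ratio of 4.58 ± 0.36 (SE, 3 arrays, 95% interval 3.59 to 5.57) and SAPCD2 4.54 ± 0.43. MSANTD4 had 3.81, CXCR2P1 3.65, MT1JP 3.53, BUD23, a methyltransferase of ribosomal RNA, 3.46, S100PBP 3.43 and OR2A7, an olfactory receptor, 3.33. CHD5, a chromatin remodeller, had 2.80, FOXP2, a transcription factor, 2.77, GIGYF2 2.65 and ARHGAP6 2.54. Below 0, IGF2BP2, an RNA-binding protein, had -2.90 ± 0.49, XXYLT1, a xylosyltransferase, -2.88 ± 0.37, and ZNF706 -2.73 ± 0.47. NDUFA11, a subunit of respiratory complex I, had -2.73, TBC1D26 and KRT75 -2.67 each, FERMT3, an integrin activator of blood cells, -2.51, ZNF701 -2.43, TPI1P2 -2.40, TMED10P1 -2.38, RING1, a Polycomb protein, -2.36 and UBE2S, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, -2.23. All 24 had the same sign on 3 of 3 arrays, which the rule of choice required. All missed the threshold, at an adjusted p of 0.0652 each by limma. Genes with larger p shared that value, among them TOP2B at an unadjusted limma p of 0.00884. Of the 12 genes above 0, 8 were measured by 1 feature, as were 9 of the 12 below.

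By limma, 0 of 12550 genes were past an adjusted p of 0.05 above 0 and 0 below. At an unadjusted p under 0.05 there were 3819 genes above 0 and 770 below, with each array centred on its median over features 104 above and 2860 below, and with each centred on its median over tested genes, a choice made after seeing the data, 1218 above and 1928 below, so that split followed the zero point. A 1-sample test without moderation called 12 genes above 0 and 2 below, and limma on each of 23308 features, those without a gene name included, called 5211 above and 761 below. Limited to the 16124 features with a gene name, a choice made after seeing the data, it called 2944 above and 310 below.

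Genes of the DNA damage and cell death programmes, which DNA breaks engage, did not pass the threshold either with the values as deposited. Among p53 target genes, 6 of 24 measured members lay above the array medians and 18 below, with a median relative log2 ratio of -0.83 (camera adjusted p = 0.302). In 2 settings chosen after seeing the data the list passed on the lower side, with each array set to 0 at its most repeated value (adjusted p = 0.0445) and with each stretch at its better displacement and centred (0.0423), but not with an estimated correlation there (0.675 and 0.496). GADD45A, a growth arrest gene, had a mean log2 ratio of 1.83 and TRIAP1, an inhibitor of apoptosis, 1.75. Pro-apoptotic genes had a median of -0.51 relative to the arrays (11 above, 21 below, adjusted p = 0.861), with BNIP3 at 2.08 and ENDOG at 1.93 as deposited. Anti-apoptotic genes had -0.28 (13 above, 15 below, adjusted p = 0.934), with the co-chaperones BAG3 at 2.03 and BAG4 at 1.97. DNA damage checkpoint and repair genes had 0.05 (18 above, 16 below, adjusted p = 0.627), with the checkpoint kinase ATR at 1.96 and the end-joining factor XRCC5 at 2.05. Topoisomerases and drug efflux genes had -0.35 (adjusted p = 0.759), with TOP2B, a target of etoposide, at -1.69 and the efflux pump ABCB1 at 2.22 (1.39 without array 2). Adjusted over the list alone, against a log2 ratio of 0 as deposited, 0 genes passed in each of these 5 lists.

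Cell cycle genes of the G2 to M phase had the highest median of the 33 lists reported, 0.46 relative to the arrays (14 of 23 above, adjusted p = 0.280). MKI67, a proliferation marker, had a log2 ratio of 1.99 and BUB1, a spindle checkpoint kinase, 2.01. G1 to S genes had -0.12 (adjusted p = 0.934), with the replication factors CDC6 at 2.17 and CDC45 at 1.98. CDK inhibitors and growth arrest genes had 0.05 (adjusted p = 0.884), with TOB1 at 1.95. Histone genes had -0.65 (5 above, 18 below, adjusted p = 0.0749), with H2BC5 at 3.01 and H2BC10 at -2.23; without array 2 the list passed (adjusted p = 0.0231), but not with an estimated correlation there (0.944) or on all arrays (0.881). Over all genes tested 0 passed in these 4 lists; adjusted over the list alone, against 0 as deposited, 7 G2 to M, 5 G1 to S, 4 growth arrest and 7 histone genes passed.

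Ribosomal protein genes were the 1 list past the threshold, on the lower side: 46 of 53 lay below the array medians and 7 above, with a median relative log2 ratio of -0.89 (camera adjusted p = 0.00698). The list's median was -0.63, -1.33 and -1.43 relative to arrays 1, 2 and 3. With an estimated correlation of 0.262 the call was lost (adjusted p = 0.881), and without array 3 it was lost too (adjusted p = 0.181). The members with the smallest p were above 0 as deposited, RPS23 at 2.01 and RPL27 at 1.75, and 0 members passed, also adjusted over the list alone. With an estimated correlation, 0 of 34 lists passed. That setting can raise p also where the estimated correlation is low. Histone genes had an estimated correlation of -0.027, below the preset 0.01, yet their unadjusted camera p rose from 0.0044 to 0.0879. For ribosomal protein genes, whose estimated correlation was far above the preset, the unadjusted camera p rose from 0.000205 to 0.354. The histone genes do not tell how much of that rise came from the correlation, which may be enough to lose the call.

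Stress and metabolic lists mostly had medians below those of the arrays, as did 26 of the 33 lists reported; the median of all tested genes was -0.13 on this scale, with 54.3% of them below 0, and 23 lists had a median below that. None of the stress and metabolic lists passed with the values as deposited. With each stretch at its better displacement, a setting chosen after seeing the data, heat shock protein genes passed on the lower side (adjusted p = 0.00679), and once centred so did they (0.0146) and unfolded protein and integrated stress response genes (0.0423); neither did with an estimated correlation (0.584, and 0.496 once centred). Unfolded protein and integrated stress response genes had -1.02 relative to the arrays (19 of 26 below, adjusted p = 0.162), with DDIT4 at 1.84 and ERN1, a stress sensor, at 1.87 as deposited. Heat shock protein genes had -0.89 (adjusted p = 0.302; HSPH1 at 2.01), oxidative stress and metallothionein genes -0.63 (adjusted p = 0.445; AKR1B10 at 2.86 and SRXN1 at 1.96), and autophagy and lysosome genes -0.70 (adjusted p = 0.200; ATG9A at 2.04 and ATG10 at 2.02). Proteasome genes had -0.47 (adjusted p = 0.557; PSMD12 at 1.78 and PSMD14 at 1.99) and EGFR and MAPK feedback genes -0.51 (adjusted p = 0.627; HBEGF at 2.06 and IER2 at 1.72). Cholesterol and fatty acid synthesis genes had -0.72 (camera adjusted p = 0.302), with SC5D at 1.86 and NSDHL at 2.36 (1.92, 1.72 and 3.44 on arrays 1, 2 and 3). Glycolysis and hypoxia genes had -0.68 (adjusted p = 0.509). Respiratory chain genes had -0.26 (adjusted p = 0.807), with NDUFC2 at 2.24 and ATP5MC3 at 1.88. Adjusted over the list alone, against 0 as deposited, 3 heat shock, 4 oxidative stress and 2 autophagy genes passed, and 0 in the other lists of this group.

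Inflammatory and secreted factors did not pass. NF-kB and inflammatory cytokine genes had a median of -0.60 (9 above, 17 below, adjusted p = 0.715), with the chemokine CCL5 at 2.78 and CSF1 at 2.24. Senescence-associated secreted factors had 0.20 (adjusted p = 0.807), with CXCL8 at 1.86 and CXCL2 at -1.90. Interferon-stimulated genes had 0.17 (adjusted p = 0.822), with IFIT1 at 2.01 and RSAD2 at 2.46. Adjusted over the list alone, against 0 as deposited, 5 NF-kB genes passed and 0 in the others.

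Lists of cell adhesion, shape and cell identity did not pass with the values as deposited. Epithelial junction genes had -0.48 relative to the arrays (9 above, 16 below, camera adjusted p = 0.349), with E-cadherin, CDH1, at 2.09 and EPCAM at 3.18. EPCAM was measured by 1 feature, at 2.06, 5.15 and 2.34 on arrays 1, 2 and 3. Mesenchymal transition genes had -0.22 (adjusted p = 0.861), with AXL at 1.94 and LOX at 1.78. Actin cytoskeleton and focal adhesion genes had -0.52 (adjusted p = 0.475; MYL6 at 1.87 and CALD1 at 1.85). Extracellular matrix and protease genes had -0.40 (adjusted p = 0.759; THBS2 at 1.85 and TIMP3 at 1.83). Basal keratinocyte-type and basal mammary genes had -0.13 (adjusted p = 0.936; FAT2 at 2.02 and MME at 1.91), luminal mammary genes -0.12 (adjusted p = 0.884; SCGB2A2 and KIT at 1.87 each) and squamous differentiation genes 0.11 (adjusted p = 0.807; S100P at 2.85 and KRT4 at 2.02). Adjusted over the list alone, against 0 as deposited, 4 basal, 7 luminal and 6 squamous genes passed, and 0 in the other 4 lists.

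Markers of cell types other than epithelium gave no call. Leukocyte genes had -1.15 (adjusted p = 0.208; CD8A at 1.92 and CD37 at 1.76), fibroblast and stromal genes -0.58 (adjusted p = 0.807; DCN at 1.77 and COL1A2 at 2.34, or 1.50 without array 3), and endothelial and adipocyte genes 0.00 (adjusted p = 0.509; CD36 at 2.10 and FABP4 at 1.50). Striated muscle genes, the tissue where obscurin is best known, had -0.48 (adjusted p = 0.627; LDB3 at 2.11 and ACTN2 at 2.05), and 11 of 31 passed adjusted over the list alone, against 0 as deposited. In the other 3 lists 0 did.

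**Figure D3:**
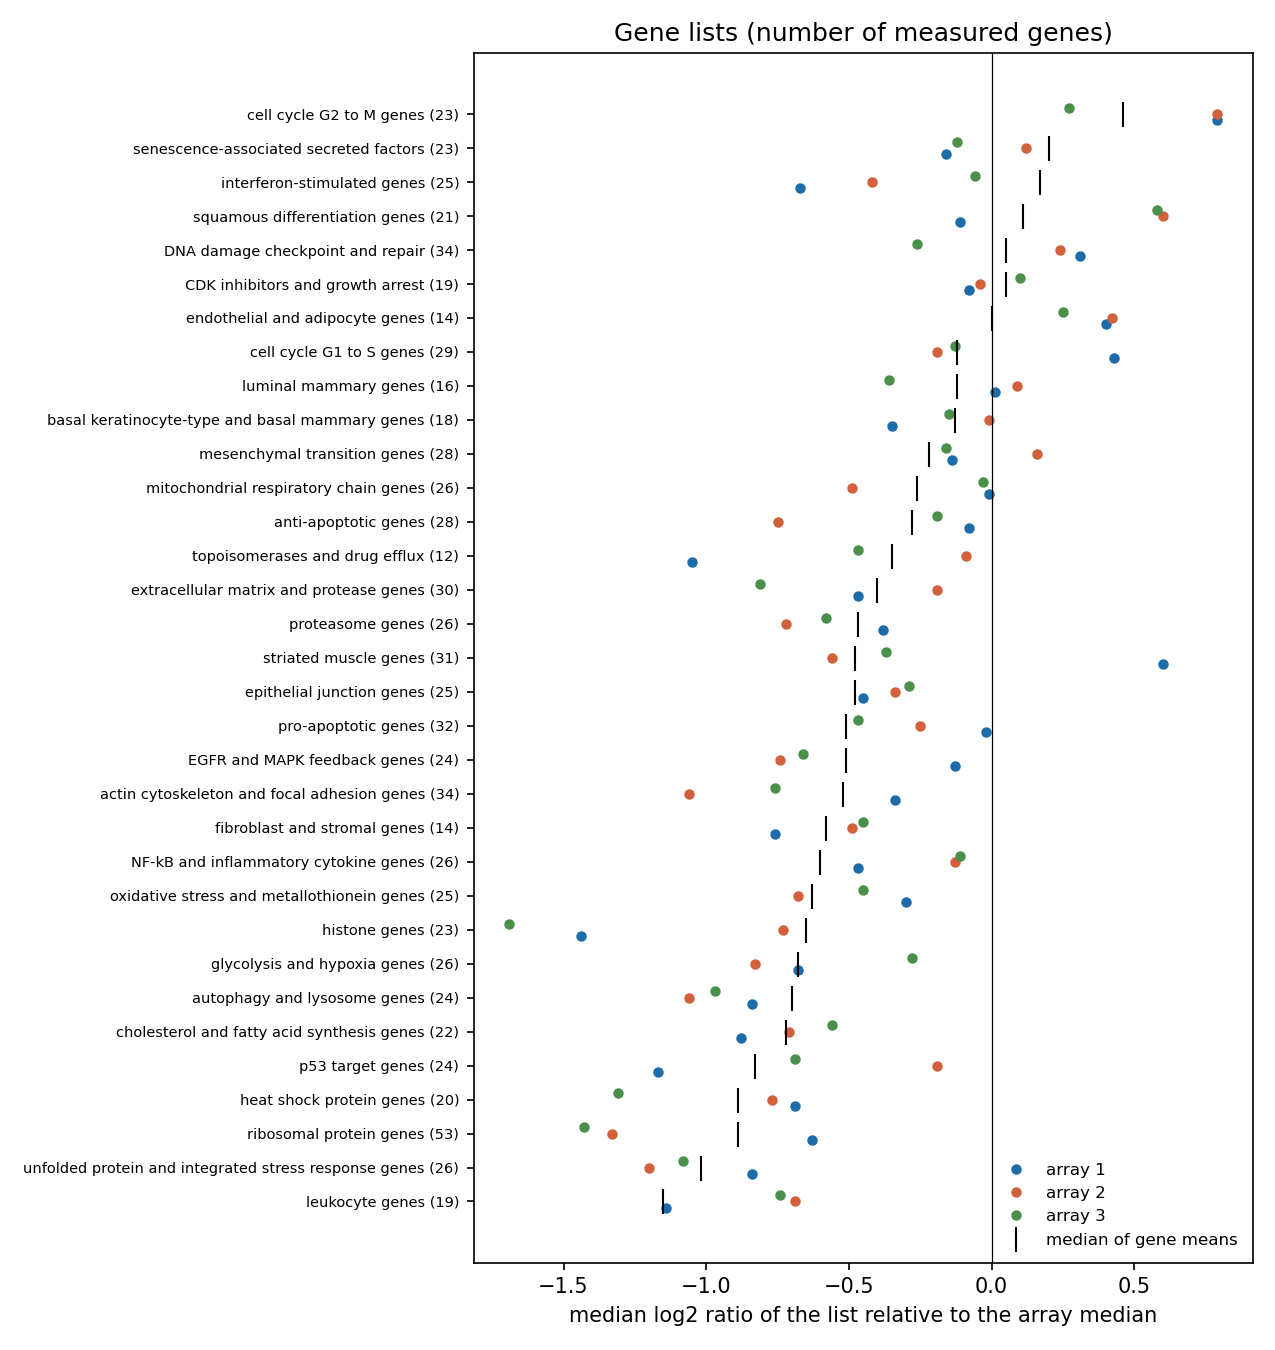
Median log2 ratio of each gene list relative to the array's median over tested genes (x axis, log2), 1 row per list with its number of measured genes, a point per array and a bar at the median of gene means. Medians run from -1.15 for leukocyte genes to 0.46 for G2 to M genes, and ribosomal protein genes lie at -0.89.

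Of the 62 list members named, 59 had a mean above 0 as deposited, and 53 lay within 0.5 of the most repeated value, whose mean over arrays was 2.01. Values and passes therefore depended on the zero point. With each array centred on its median over tested genes, the 59 had a median of 1.08 instead of 1.98, and 46 of the 62 had an unadjusted p under 0.05 instead of 62. Adjusted over each list alone, 53 passes above 0 and 12 below, in 12 lists, became 0 above and 53 below, in 15 lists. With each array centred on its median over features, which left the tested genes at a median of -0.61, these numbers were 0.60, 7 of 62, and 0 above and 126 below, in 27 lists. The median, the mean and the test differed in sign in 6 lists, which were CDK inhibitors and growth arrest, interferon-stimulated, mesenchymal transition, basal, endothelial and adipocyte, and respiratory chain genes.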

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

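Settings limited to the first stretch, and those named above as added, were chosen after seeing the data. Counts of genes past the threshold stayed at 0 above and 0 below under centring on features or tested genes, scaling and quantile normalization. Values on at least 2 arrays, median of spots, robust eBayes, array weights and leaving out any 1 array gave 0 too. Dropping top values or partly valued spots, the first stretch as deposited, and each stretch at its better displacement, centred or not, gave 0 too. The minimum mean, also 0, can only remove genes. The simulated test recovered 0 genes even at a log2 ratio of 6, so these zeros show neither robustness nor absence of change. Testing each feature on its own, those without a gene name included, gave 5211 above and 761 below, those with a gene name alone 2944 and 310, and the 1-sample test without moderation 12 and 2. For the features the smallest adjusted p by limma was 0.0444 and 0.0489, close to the threshold. Setting each array to 0 at its most repeated value gave 2 above and 2161 below with 2 lists (ribosomal protein and p53 target genes), and the first stretch with array 1 taken 1 row earlier gave 536 above and 123 below with 2 lists (ribosomal protein, and autophagy and lysosome genes), falling to 0 and 0 once centred. The number of lists called was 0 with an estimated correlation, 0 with fry and 0 to 2 leaving out 1 array. It was 2 with each stretch at its better displacement (ribosomal and heat shock protein genes) and 6 once that was centred, adding p53 target, histone, actin cytoskeleton and focal adhesion, and unfolded protein and integrated stress response genes, all on the lower side. With an estimated correlation none of the lists named for these 4 settings passed (adjusted p 0.675, 0.755, 0.584 and 0.496 in this order, but 0.519 for histone genes). The camera direction of uncalled lists turned for cell cycle G1 to S genes (adjusted p 0.900 centred, 0.912 scaled), CDK inhibitors and growth arrest (0.750 and 0.758), senescence-associated secreted factors (0.742 and 0.733) and mesenchymal transition genes (0.742 and 0.733). It turned for luminal mammary genes on ranks (0.982) and anti-apoptotic genes with spots valued on all arrays (0.954). In each added setting of zero point, place or stretch, 3 to 6 uncalled lists turned (0.146 to 0.989). It turned in at least 1 fit without 1 array for basal keratinocyte-type and basal mammary genes (range 0.956 to 0.986), anti-apoptotic genes (0.858 to 0.919), mesenchymal transition genes (0.790 to 0.996), cell cycle G1 to S genes (0.867 to 0.956) and CDK inhibitors and growth arrest (0.842 to 0.959). All 86 named genes kept their sign under every setting planned and run for them: centring, scaling, quantile normalization, the median of spots, robust eBayes, array weights and leaving out each array. For the last 3 settings this was fixed in advance and shows no stability. Each named gene had the same sign on every array, so leaving out or weighting arrays could not turn its mean. Robust eBayes does not change the mean. Their values moved with the zero point: the median of the 71 above 0 fell from 2.02 to 0.63 centred on the features and 1.11 on the tested genes, and with each array set to 0 at its most repeated value 33 of 86 changed sign. Except for the choices whose construction changes the zero point or the features used, the cause was not tested. No paired analysis was possible because each array is already 1 pair of cultures. Signal over background was not analysed here.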

Other observations

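Every test in this part was chosen after the result was seen.

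In the first 9044 features, with array 1 taken 1 row earlier and each array centred on its gene median, 1588 of 2713 genes had the same sign on 3 of 3 arrays, 779 above and 809 below, against 1282 of 2757 with array 1 at its own place; the place was chosen for its agreement with arrays 2 and 3, so part of this gain follows from the choice. By limma 0 genes passed, with 367 above and 616 below at an unadjusted p under 0.05. The 6 genes with the smallest p there were ICAM1, a leukocyte adhesion receptor, at -3.74 ± 0.46 (SE) relative to the array medians, TUFM, a mitochondrial elongation factor, at -2.85, SLC35E2A at -3.10, SRSF5, a splicing factor, at -2.95, TCF7L2 at -2.92 and RNASE7 at -2.81, each with an adjusted p of 0.0583. These genes were chosen after their values were seen. Ribosomal protein genes passed there (26 genes, camera adjusted p = 1.75e-06), and were lost with an estimated correlation (adjusted p = 0.723).

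Features of one transcript disagreed within arrays, although the arrays shared part of their order. Spot noise alone would leave no displaced place better than the own place; on array 3, last stretch, the correlation was higher 1 row earlier by 0.297 ± 0.067 (SE). A displacement of the whole table would leave no agreement at the own place; on array 2, first stretch, the intraclass correlation of repeated features exceeded that 1 row earlier by 0.680 ± 0.079. A displacement by 1 feature row is a candidate explanation for the first stretch of array 1, where the gain 1 row earlier was 0.310 ± 0.074 and features of other transcripts then correlated with array 2 at 0.410 instead of 0.185. In stretch 2, moving array 1 lowered its correlation with array 2 from 0.328 to 0.231. Array 2 itself agreed there at both places, at 0.362 ± 0.054 at the own place and 0.268 ± 0.053 at 1 row earlier. Moving 1 array therefore cannot decide that stretch. A displacement of the whole last stretch does not alone account for its values. Array 2 but not array 1 agreed better 1 row earlier there, yet taking array 2 there changed their correlation by -0.075 ± 0.020 (array 3 by -0.035 ± 0.020). A displacement that begins within a stretch was not tested. What else contributes, and whether any biological explanation applies, was not tested either.

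Most deposited ratios lay above 0. A change of most expressed genes, higher in cells with obscurin shRNA or, if the ratio was formed the other way, lower in them, would put translation factor genes, abundant in all cells, above olfactory receptor genes, which breast epithelium does not use; in the first stretch with array 1 taken 1 row earlier, the difference of their medians was -2.40 ± 0.72 (log2, SE), and over all features as deposited -1.0 ± 0.23. A scaling constant that moved features without signal to about 2 stays open: the share of features within 0.5 of the most repeated value differed between families little or not used in breast epithelium and other named features by 1.1 ± 4.1 percentage points there and 2.5 ± 1.7 over all features. Gene names were not borne out over much of the arrays, so this comparison cannot settle it. The distance of 16.61 between the highest and the most repeated value would arise from such a constant. It does not tell whether features near 2 lack signal. A dye effect stays open, because 0 arrays had the dyes exchanged.

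Ribosomal protein genes lay below the other genes. Whether lower ratios of abundant transcripts as a class account for this stays open. In the first stretch with array 1 taken 1 row earlier, 4 sets together lay at -0.35 ± 0.47 from the other lists, and over all features at -0.29 ± 0.10. These were translation factor, glycolysis and hypoxia, proteasome and respiratory chain genes. The glycolysis and hypoxia list also holds hypoxia genes such as VEGFA and ADM, so it was not chosen for abundance alone. The next values are medians over features of that first stretch. They are relative to the array medians over its named features, not over tested genes as for the lists above. Translation factors lay at -2.01 ± 0.69 but glycolysis and hypoxia genes at -0.41 ± 0.49. EGFR and MAPK feedback genes, not chosen for abundance, lay at -2.49 ± 0.59. A change of ribosomal protein genes beyond other abundant genes stays open too, because the abundance of each transcript was not examined here: their median minus that of translation factors was -0.57 ± 0.72 there and -0.59 ± 0.30 over all features, and minus that of the 4 sets together -1.63 ± 0.47 and -0.67 ± 0.23. No array with exchanged dyes tests whether the shift comes from the dyes or the shRNA.

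Turning the sign of 1 array at a time gives 4 distinct arrangements of the 3 arrays, too few for a share under 0.05. The real arrangement called 0 genes and the highest of the others 30. For lists, the real arrangement called 1 and the highest other 1.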
